A study of Rattus norvegicus with 12 samples.

How the data were processed

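Total RNA of calvarial bone from 10-week-old rats, taken 24 h after surgery, was labelled with Cy3 from 200 ng and hybridised to 12 single-colour Agilent arrays, per the labels' protocols. The labels name 4 bur-drilled, 4 laser-ablated and 4 control samples with the numbers 1 to 4. They do not say whether the samples of a group came from separate animals, so p-values here measure only the spread between these samples. No arrays were duplicates: the closest pair within a group correlated at 0.989 across genes.

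The deposited scanner files hold an intensity per spot, written by Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes. Its processed signal is background-corrected, and flags mark spots that are outliers, saturated or well above background, per the file headers. Each array had 62976 spots, of which 4259 were controls. No spot was saturated. The number of arrays limits the precision, and there are no counts behind the values. The authors' deposited expression table holds log2 values, named as quantile normalized in its title. Its first 21080 of 24920 entries were rebuilt from the scanner files within 1e-06 by normexp with an offset of 16 on the spot median, quantile normalization, and a filter on spots above 1.1 times the 95th percentile of the negative controls on at least 4 arrays. The last 3840 entries could not be rebuilt. Their deviations between arrays correlated at a median of 0.222 with those of the probe of the same name, against 0.894 for the rebuilt ones, so they were not used. The authors' deposited comparison results hold log2 fold changes, p-values and adjusted p-values for 21080 entries, whose columns are those of limma and whose adjustment is that of Benjamini and Hochberg, per the file headers and values.

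The processed signal was taken to log2 and quantile normalized between arrays, since the title of the authors' values names that method. Control spots and outlier spots were left out and spots of 1 probe were averaged. Of 45598 rat probes, 27196 were kept because they were well above background on at least 4 of the 12 arrays, whichever the group. Through the accessions, 21184 probes were named from RefSeq gene names of the GRCr8 assembly, of which 2431 received another symbol than the file gave. A further 14713 kept the file's name and 9701 had no symbol. A gene with several kept probes was represented by the probe with the highest mean, which left 16382 genes, 4748 of them with more than 1 kept probe. The probes of a gene often differed. Where those of a gene named for a comparison differed in call or by over 1.5 times in log2 fold change, their values are given.

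All 12 arrays entered 1 limma fit (lmFit, contrasts, eBayes), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. For Sost an exact two-sided permutation test was added in each of the 3 comparisons. A gene not well above background on any array of a group has only a bound there. Its fold is then given as at least the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Such a bound holds for the processed signal as normalized here, and other background corrections can give a smaller fold. For named genes that only some arrays of a group read well above background, the number of these arrays is given, and where raising the dimmer arrays to that limit changes the value, also the value so obtained, computed after the values were seen.

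Before the data were examined, 25 gene lists were fixed. They cover inflammatory cytokines and chemokines, neutrophil, monocyte and macrophage, lymphocyte, erythroid, osteocyte, osteoclast, endothelial, periosteal and fibroblast, chondrocyte, skeletal muscle, adipocyte, neural and epidermal markers. They also cover osteoblast and bone matrix genes, Wnt targets, secreted Wnt antagonists, YAP and TAZ targets, heat shock, hypoxia and glycolysis, cell cycle, interferon-stimulated, matrix remodelling and wound, BMP and TGF-beta pathway and oxidative phosphorylation genes. Sost and Dkk1 stand in both the osteocyte and the Wnt antagonist list, and Tgfb2 in both the BMP and TGF-beta and the YAP and TAZ list. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and comparisons, and again with an estimated correlation and with fry.

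The genes named were also set by a rule fixed before the data were examined. For each comparison these are the 8 highest and 8 lowest log2 fold changes among called genes with a symbol whose 4 values in 1 group all lie above the 4 in the other. To them come up to 4 members of each described list with the smallest p, and Sost. Some of the genes that the rule takes are not reported here. A subset is printed. For bur against control the calls of S100a9 and Mepe proved to hang on single arrays, and their values are given with that limit. Genes outside the rule are marked as chosen after their values were seen.

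The limma step was tested on simulated data of 16375 genes with 200 changed genes per comparison. At 1.5-fold, 2-fold and 4-fold it recovered 13.4%, 47.8% and 81.8% of the changed genes for bur against control, with 5 false calls. It recovered 8.96%, 43.3% and 78.8% for laser against control, with 3 false calls, and 16.4%, 50.7% and 81.8% for laser against bur, with 10. In simulated bur against control data camera called the 1 shifted list and 0 others. The simulated genes were drawn independently, whereas the lists' estimated correlations in the real data ran from 0.0944 to 0.818 (median 0.272). Each simulated gene also had the same spread in all groups, whereas the median correlation between real arrays was 0.981 within laser and 0.958 within control. The simulation therefore does not measure false gene or list calls in these data.

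Slide and scan were read from the files. The slide as a block was not run, because each laser comparison lies across slides that hold no group in common and the bur and control arrays share a slide. Alternatives were scaling to the 75th percentile, normexp background correction with an offset of 50, the authors' deposited log2 values, no filter or a filter on all 12 arrays, the mean of a gene's probes, every probe on its own, a fit of only the 2 groups, the replicate number as a block, array weights, trend and robust moderation, a 2-fold threshold, and leaving out each array. Leaving out control 1 and control 4, and counting genes whose probes were all called the same way, were added after seeing the data. The numbers of the samples, which are also the rows on the slides, were not taken as pairs. For the tests of explanations, what each explanation predicts was written down before its value was seen, except for those named in the closing section, and the 95% intervals set beside the predictions were added after the values were seen. The versions were R 4.3.3, limma 3.58.1, jsonlite 2.0.0 and, for data.table, 1.17.8. A genome was not given, so probe positions are those of the files on rn4.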

Results

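Gene expression was measured in calvarial bone of 10-week-old rats 24 h after surgery, on 12 single-colour Agilent arrays. The arrays formed 3 groups of 4. In the bur group a defect of 8 by 3 mm was drilled with a rotating bur fed at about 0.75 mm/s. In the laser group a defect of that size was made with 3 strokes of an Er:YAG laser, an erbium laser whose light is strongly absorbed by water, at 20 Hz, 127 mJ per pulse at the tip and about 2 mm/s. In the control group the periosteum, the membrane that covers bone, was removed and the bone was left whole. After filtering, 16382 genes were tested in each comparison.

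Signal before normalization differed between the groups. The median processed signal was 67.1 ± 11 (SD, n = 4) on laser arrays, 22.3 ± 4.18 on bur arrays and 28.7 ± 12.4 on control arrays. Of all spots, 69.5% ± 1.90, 58.1% ± 1.29 and 61.0% ± 3.4 were well above background in these groups. All bur and control arrays lay on slide 1, in separate columns, and all laser arrays lay on slide 2, scanned separately. Bur and control bone were therefore compared within 1 slide, where column and treatment cannot be told apart. In both laser comparisons slide and treatment cannot be told apart. The first principal component held 32.8% of the variance and set laser arrays (-72.3 to -51.6) apart from bur (-2.56 to 19.4) and control arrays (38.8 to 64.6). Across genes, which are not independent replicates, the median correlation between arrays was 0.972 within bur, 0.958 within control and 0.981 within laser, against 0.943 between bur and control, 0.946 between bur and laser and 0.935 between control and laser.

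Sost, which encodes sclerostin, a Wnt antagonist secreted by osteocytes, is named in the title of the series, which asks about lower Sost after Er:YAG irradiation. Its level was 5.16 ± 0.63 log2 (SD, n = 4) in laser-ablated bone, 5.59 ± 0.82 in control bone and 5.79 ± 0.78 in bur-drilled bone. The laser arrays read 5.23, 5.76, 5.37 and 4.27, the control arrays 5.63, 6.35, 5.93 and 4.45, and the bur arrays 4.90, 5.44, 6.69 and 6.12. The log2 fold change was -0.44 ± 0.48 (SE) for laser against control (limma adjusted p = 0.513, exact two-sided permutation p = 0.400), with a 95% interval of the fold from 0.356 to 1.53. It was -0.63 for laser against bur (adjusted p = 0.375, exact permutation p = 0.257), with an interval from 0.311 to 1.34. It was 0.20 for bur against control (adjusted p = 0.803, exact permutation p = 0.743), with an interval from 0.551 to 2.38. The smallest p this permutation test can give with 4 against 4 arrays is 0.0286. No difference in Sost was detectable with these arrays, and the intervals include no change as well as a fall to 0.356 of the control level. The sign for bur against control turned without bur 3 (-0.10) and without control 4 (-0.18), under 75th percentile scaling (-0.14) and without control 1 and control 4 (-0.35). For laser against control the value was -0.99 without those 2 arrays and -0.06 with array weights, neither called. The authors' deposited tables gave -0.27 for laser against control (adjusted p = 0.458), -0.25 for laser against bur (adjusted p = 0.512) and -0.01 for bur against control (adjusted p = 0.977).

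The level of Sost was read by 1 kept probe, A_64_P124671, of sequence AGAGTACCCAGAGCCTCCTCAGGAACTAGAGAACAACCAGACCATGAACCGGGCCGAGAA, which was well above background on 12 of 12 arrays. The deposited files place it on chromosome 10 from 91026551 to 91026610 of the rn4 build. An annotation of that build was not used here, so its exon is not given.

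**Figure D1:**
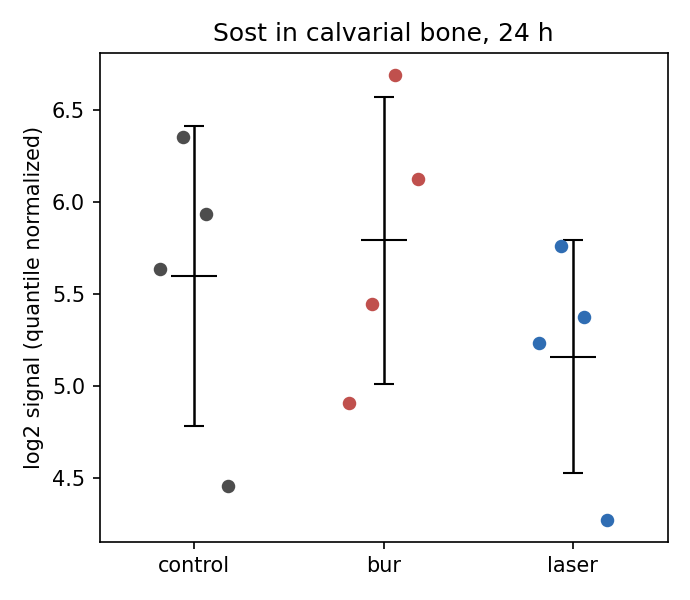
Quantile normalized log2 signal of Sost (y axis) on each array of the control, bur and laser groups (x axis), with the mean and SD of the 4 arrays as a dash and bar. The 3 groups overlap, with means of 5.59, 5.79 and 5.16.

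Bur drilling was compared with periosteum removal alone to find what drilling changes in the bone after 24 h. Ccl12 and Ccl7 rose most among the named genes. Ccl12, Ccl7 and Ccl2, chemokines that draw monocytes, rose 36.6-fold, 36.1-fold and 19.8-fold, with log2 fold changes of 5.20 ± 0.65, 5.17 ± 0.45 and 4.31 ± 0.42 (SE, n = 4 per group). Cxcl1, a neutrophil chemokine, rose 23.1-fold, and Acod1, the enzyme that makes itaconate in activated macrophages, rose 30.4-fold. Wfdc21, Dmkn and Gsg1 rose 23.2-fold, 21.0-fold and 19.2-fold. Of the 4 control arrays 1 read Acod1, 2 read Wfdc21 and 3 read Dmkn well above background, and with control arrays held at no less than the lowest signal well above background, called the background limit here, the folds were 27.1, 18.1 and 21.0. The adjusted p of these 8 genes ran from 0.000251 for Ccl7 to 0.00421 for Gsg1. With normexp background correction the log2 fold changes were smaller, at 2.13 for Acod1, 1.88 for Wfdc21, 2.43 for Dmkn and 2.85 for Cxcl1, and each was still called.

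In the list of inflammatory cytokines and chemokines, 14 of 20 genes rose, 1 fell and 5 did not pass the test. Adjusted over the list alone, 17 were called. Ccl3, a macrophage chemokine, rose 14.5-fold and Tnf 5.33-fold, whereas Csf3, a granulocyte growth factor chosen after its value was seen, fell by 1.15 on the log2 scale. The list was called by camera (adjusted p = 3.90e-05, and adjusted p = 0.544 with an estimated correlation). Of 13 monocyte and macrophage markers, 9 rose and 4 did not pass (11 when adjusted over the list alone), among them Cd14, a receptor for bacterial lipopolysaccharide, at 6.90-fold and the scavenger receptor Msr1 at 10.3-fold. That list had camera adjusted p = 8.44e-05, and adjusted p = 0.544 with an estimated correlation.

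Hypoxia and glycolysis genes rose together in bur-drilled bone, with 12 of 16 members higher and 4 not passing (13 when adjusted over the list alone). Pdk1, which limits pyruvate use in mitochondria, rose 3.04-fold and the glycolytic enzyme Hk2 rose 3.16-fold. Camera gave adjusted p = 3.90e-05, and adjusted p = 0.683 with an estimated correlation. Of 14 interferon-stimulated genes, 11 rose, 1 fell and 2 did not pass (13 when adjusted over the list alone). The RNA sensor Ddx58 rose 3.13-fold and Oas1a 3.04-fold, while the antiviral enzyme Rsad2 fell by 1.34 on the log2 scale. The list had camera adjusted p = 0.000578, and adjusted p = 0.708 with an estimated correlation. With normexp the log2 fold change of Ddx58 was 0.99, and with the authors' deposited values that of Pdk1 was 1.04.

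Cell cycle and erythroid genes fell in bur-drilled bone. Of 19 cell cycle genes, 18 fell and 1 did not pass (19 when adjusted over the list alone), with log2 fold changes of -1.42 ± 0.14 (SE) for Ccnb2 and -1.30 ± 0.14 for Ccna2, cyclins that drive mitosis. By camera the list had adjusted p = 5.28e-16, and adjusted p = 0.544 with an estimated correlation. Of 12 erythroid markers, 11 fell and 1 did not pass (11 when adjusted over the list alone). Klf1, a transcription factor of red cell precursors, had a log2 fold change of -1.59 ± 0.19 and the red cell anion exchanger Slc4a1 one of -1.94 ± 0.27. The list had camera adjusted p = 1.25e-08, and adjusted p = 0.544 with an estimated correlation.

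Some matrix remodelling, periosteal and BMP and TGF-beta pathway genes were also higher in bur-drilled than in control bone. Of 15 matrix remodelling and wound genes, 9 rose and 6 did not pass (11 when adjusted over the list alone), with the membrane-bound collagenase Mmp14 at 1.75-fold. Camera gave adjusted p = 4.26e-05, and adjusted p = 0.544 with an estimated correlation. Of 12 periosteal and fibroblast markers, 5 rose and 7 did not pass (6 when adjusted over the list alone), among them Aspn at 10.7-fold, read well above background on 2 of 4 control arrays, and the collagen gene Col3a1 at 3.82-fold. For that list camera gave adjusted p = 0.0406, and adjusted p = 0.755 with an estimated correlation, and it was not called without bur 2 (adjusted p = 0.0576), bur 3 (0.0738), bur 4 (0.0728), control 3 (0.101) or control 4 (0.0622), with normexp (0.0958), with the authors' deposited values (0.0985), among probes well above background on all 12 arrays (0.131) or without control 1 and control 4 (0.0576). Prrx1, a transcription factor of skeletal progenitors chosen after its value was seen, was the fifth member, at 0.99 log2. Of 15 BMP and TGF-beta pathway genes, 3 rose and 12 did not pass (3 when adjusted over the list alone), among them Skil at 1.87-fold and Tgfbi at 4.17-fold. For it camera gave adjusted p = 0.0152, and adjusted p = 0.600 with an estimated correlation, and the call was lost without the filter on dim probes (adjusted p = 0.0583). With normexp the log2 fold change of Aspn was 1.31, which was still called.

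The 8 genes that the naming rule took as lowest against control included several known from nervous tissue. Cdhr1, a photoreceptor cadherin, fell by 4.03 ± 1.11 (SE) on the log2 scale, and Slc7a10, an amino acid transporter of brain and fat, fell by 3.70 ± 0.81. Slc7a10 was well above background on 1 of 4 bur arrays, and with bur arrays held at no less than the background limit the log2 difference was -2.35. For 6 of the 8 no bur array was well above background. Of these, Slc1a2, a glutamate transporter of astrocytes, was at least 3.59-fold lower, Dnajc6 at least 3.57-fold, Frmpd1 at least 2.95-fold and the glycerol channel Aqp7 at least 2.22-fold, of which Slc1a2, Frmpd1 and Aqp7 were well above background on 3 of 4 control arrays. Of 7 neural markers, 2 fell and 5 did not pass (2 when adjusted over the list alone), with camera adjusted p = 0.00738, and adjusted p = 0.646 with an estimated correlation. Gfap, an astrocyte filament protein, was at least 1.46-fold lower, read well above background on 2 of 4 control arrays. Myelin gene Mbp read 13.29 and 12.37 log2 in control 1 and control 4, 7.87 and 8.14 in control 2 and control 3, and between 6.22 and 9.92 in the bur arrays.

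Several of these calls were lost without control 1 and control 4, which leaves fewer control arrays. Without both arrays, an alternative chosen after seeing the data, Cdhr1 (-1.89), Slc7a10 (-3.53), Frmpd1 (-2.92) and Slc1a2 (-1.95) were no longer called, nor was the neural list (camera adjusted p = 0.289, and 0.210 among probes well above background on all 12 arrays). Dnajc6 (-1.80) was smaller but still called. The call of Cdhr1 was also lost without bur 1 (-3.70), control 1 (-3.30) or control 4 (-3.33). Under normexp the log2 fold changes shrank to -0.60 for Slc7a10, -0.47 for Slc1a2 and -0.53 for Dnajc6, and Aqp7 lost its call (-0.27), as it did with the authors' deposited values (-0.52). Frmpd1 gave -0.58 with normexp and was not called with array weights (-2.88). For Slc1a2, Dnajc6, Aqp7 and Frmpd1 the normexp values were smaller than the bounds given for them. So was that of Gfap, at -0.22 with normexp against a bound of -0.54 in log2. Without the filter on dim probes Gfap (-0.75) lost its call.

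In all, 3837 genes differed between bur-drilled and control bone, 2241 higher and 1596 lower, and 1794 of them by at least 2-fold, 1056 higher and 738 lower. Taken gene by gene, 3806 genes had all 4 bur values on 1 side of all 4 control values (23.2% of the genes tested, where chance gives 2.86%). Higher genes made up 58.4% of the calls, but 40.1% (1564 higher and 2332 lower) when each array was scaled to its 75th percentile, which moved the median of all genes from 0.08 to -0.10 log2. The count was 2353, with 1122 higher and 1231 lower, without control 1 and control 4, and 2476 when only the 2 groups entered the fit. The number of lists called by camera, 10 of 25, was matched or passed in 7 of the 35 splits of these 8 arrays.

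**Figure D2:**
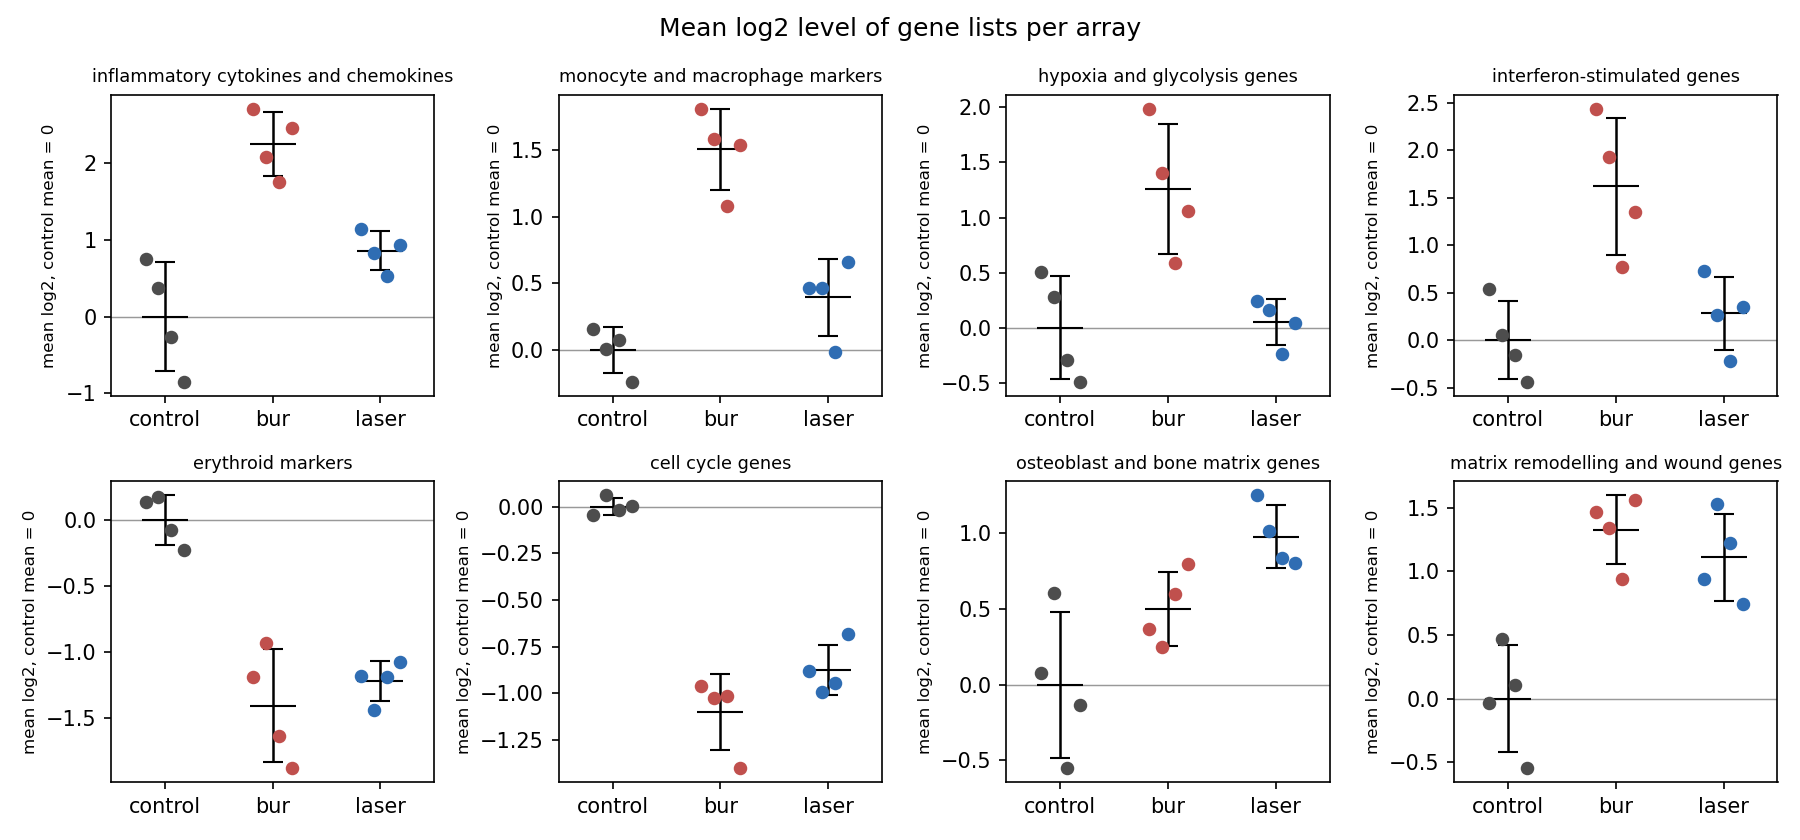
Mean log2 level of 8 gene lists on each array, with the mean of the control arrays set to 0 (y axis), in the control, bur and laser groups (x axis). Dashes and bars are the mean and SD of 4 arrays. Cell cycle genes lie between -1.40 and -0.68 on all bur and laser arrays, and cytokines between 1.75 and 2.70 on the bur arrays and between 0.52 and 1.14 on the laser arrays.

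Laser ablation was set against the same control arrays. Mcc rose 282-fold, but was well above background on 1 of 4 control arrays, and the fold was 220 with control arrays held at no less than the background limit. Ovch2, a serine protease gene, rose at least 69.0-fold, since no control array read it well above background. Krt80, a keratin, rose 86.0-fold, Mkx, a transcription factor of tendon, 69.4-fold and Foxe1, a transcription factor of the thyroid, 59.9-fold. Igfbp7, which binds insulin-like growth factors, rose at least 29.0-fold, Id3, an inhibitor of DNA binding induced by BMP signals, at least 20.0-fold, and Rps19l3 31.8-fold. Krt80 and Mkx were well above background on 3 of 4 control arrays. Mcc, Ovch2, Krt80, Igfbp7 and Id3 were each read by only 1 kept probe, so no other probe could check these folds. The adjusted p of these 8 genes ran from 3.16e-09 for Id3 to 8.85e-06 for Mcc, with SEs of 0.14 to 0.65 log2 (n = 4 per group). Of the 3 Mkx probes, the others gave log2 fold changes of 1.62 and 0.32, against 6.12 for the brightest, and the mean of them gave 2.69. Under normexp the log2 fold changes were 4.71 for Mcc, 2.74 for Ovch2, 4.21 for Krt80, 3.72 for Mkx, 1.87 for Igfbp7 and 1.49 for Id3, each still called. For Ovch2, Igfbp7 and Id3 these lay below the bounds given, which are 6.11, 4.86 and 4.32 in log2.

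Bone matrix genes rose in laser-ablated bone, with 8 of 16 osteoblast and bone matrix genes higher and 8 not passing (11 when adjusted over the list alone). Col1a2, a chain of type I collagen, rose 3.53-fold (log2 1.82 ± 0.24, SE), Alpl, the phosphatase of mineralizing bone, 2.79-fold and Runx2, the osteoblast transcription factor, 2.00-fold. The second Alpl probe gave 0.74 log2 and was not called. By camera the list had adjusted p = 0.000736, and adjusted p = 0.683 with an estimated correlation. Of 15 matrix remodelling and wound genes, 10 rose and 5 did not pass (10 when adjusted over the list alone), with the matrix glycoprotein Tnc at 2.62-fold and Plau, the urokinase gene, at 2.13-fold. That list had camera adjusted p = 0.00136, and adjusted p = 0.666 with an estimated correlation. Of 15 BMP and TGF-beta pathway genes, 7 rose, 1 fell and 7 did not pass (8 when adjusted over the list alone). Besides Id3, Ltbp2 rose 2.64-fold and Bmp7 2.57-fold, while Id2, chosen after its value was seen, fell by 0.53 on the log2 scale, its second probe giving 0.23 and not called. The list had camera adjusted p = 0.00863, and adjusted p = 0.544 with an estimated correlation. With normexp the log2 fold changes were 0.45 for Bmp7, 0.91 for Ltbp2 and 0.22 for Plau, each still called.

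Erythroid and cell cycle genes fell in laser-ablated bone. Of 12 erythroid markers, 10 fell and 2 did not pass (10 when adjusted over the list alone), with log2 fold changes of -1.28 ± 0.19 (SE) for Klf1 and -1.46 ± 0.22 for Ahsp, which stabilizes alpha globin. Camera gave adjusted p = 7.94e-05, and adjusted p = 0.666 with an estimated correlation. Of 19 cell cycle genes, 16 fell and 3 did not pass (17 when adjusted over the list alone), with -1.34 ± 0.14 for Cdk1, the mitotic kinase, and -1.35 ± 0.14 for Ccna2. The second Ccna2 probe gave -0.44 and was not called, and the authors' deposited values gave -0.86. Of the 4 probes of Mki67, a proliferation marker chosen after its value was seen and counted as lower (-1.61), 1 was called higher (1.99). For that list camera gave adjusted p = 1.25e-08, and adjusted p = 0.544 with an estimated correlation.

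The cytokine, macrophage, interferon, hypoxia and periosteal lists were not called by camera in laser against control. Of 20 cytokines and chemokines, 7 rose, 2 fell and 11 did not pass (9 when adjusted over the list alone, camera adjusted p = 0.135), with Ccl7 up 4.86-fold. The 2 that fell were Csf3, at -1.64 log2 (-1.01 with normexp), and Il33, an alarmin chosen after its value was seen, at -0.73. Of 13 monocyte and macrophage markers, 4 rose and 9 did not pass (4 when adjusted over the list alone, camera adjusted p = 0.399), among them Cd68 at 2.17-fold. Of 14 interferon-stimulated genes, 3 fell and 11 did not pass (3 when adjusted over the list alone, camera adjusted p = 0.938), with Rsad2 at -1.60 log2. Of 16 hypoxia and glycolysis genes, 1 rose, 1 fell and 14 did not pass (1 when adjusted over the list alone, camera adjusted p = 0.875). Of 12 periosteal and fibroblast markers, 6 rose and 6 did not pass (6 when adjusted over the list alone, camera adjusted p = 0.0645), and fry called that list higher (adjusted p = 0.0127). For the other 4 lists fry gave adjusted p = 0.0971, 0.122, 0.979 and 0.80, in the order given.

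The 8 genes that the naming rule took as lowest after laser ablation again included genes of nervous tissue. Hpcal4, a neuronal calcium sensor, was at least 17.6-fold lower, with 0 laser and 3 control arrays well above background. The log2 fold change was -4.19 for Itih3, -4.06 for Bcan, a proteoglycan of brain matrix, and -3.85 for Scn3b, a sodium channel subunit. It was -3.84 for C1qtnf4, -3.42 for Slc7a10 and -3.35 for Igfbp2, and the SEs of these 7 genes lay between 0.65 and 1.37. Of the 4 laser arrays, 1 read Itih3, C1qtnf4 and Slc7a10, 2 read Scn3b and 3 read Bcan well above background, and 3 control arrays read Itih3, Scn3b and C1qtnf4. With laser arrays held at no less than the background limit the log2 differences were -4.05 for Itih3, -3.71 for Scn3b, -3.56 for C1qtnf4 and -3.02 for Slc7a10. Of 7 neural markers, 1 rose, 2 fell and 4 did not pass (3 when adjusted over the list alone, camera adjusted p = 0.259), with Mag, a myelin glycoprotein, at 1.32 (1.11 and not called under 75th percentile scaling, 0.46 with normexp). As in the other comparison, Mbp was high in control 1 and control 4 (13.29 and 12.37 log2), against 7.41 to 7.81 on the laser arrays.

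Without control 1 and control 4 the calls of Hpcal4 (-1.46), Itih3 (-1.87) and Slc7a10 (-3.25, against -3.42 with all arrays) were lost. Bcan (-2.08), Scn3b (-1.64) and C1qtnf4 (-1.88) were smaller but still called. The call of Hpcal4 was also lost without control 1 (-3.34), control 4 (-3.46), laser 1 (-4.35), laser 2 (-4.34), laser 3 (-4.41) or laser 4 (-4.38), when only the 2 groups entered the fit (-4.37) and with normexp (-1.66). The normexp value of Hpcal4 was smaller than the bound given for it, which is -4.14 in log2. C1qtnf4 was not called with normexp (-1.02), nor Itih3 over the mean of its probes (-2.42), its second probe giving -0.65. Normexp gave log2 fold changes of -1.55 for Itih3, -1.60 for Bcan, -1.22 for Scn3b, -0.69 for Slc7a10 and -1.37 for Igfbp2, each still called.

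In all, 5637 genes differed between laser-ablated and control bone, 2990 higher and 2647 lower. By at least 2-fold 2514 were called, 1740 higher and 774 lower, while 5769 genes had groups that did not overlap (35.2%, where chance gives 2.86%). Over calls of any size, lower genes outnumbered higher ones under 75th percentile scaling (2455 higher, 2975 lower), among probes well above background on all 12 arrays (2046 and 2639), without control 1 (2633 and 2780) and without control 1 and control 4 (1815 and 2218). Of the called genes, 564 were not well above background on any control array, but only 1 was not on any laser array. In bur against control these numbers were 71 for control and 129 for bur arrays. The filter could be passed through the 4 laser arrays alone. The excess of higher genes at 2-fold therefore cannot be told apart from better detection on the laser arrays. Among 1753 called genes with more than 1 kept probe, 425 (24.2%) had every probe called the same way, and among the 1175 such genes of the bur comparison 472 (40.2%) did. The number of lists called, 5 of 25, was matched or passed in 28 of the 35 splits of these 8 arrays.

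**Figure D3:**
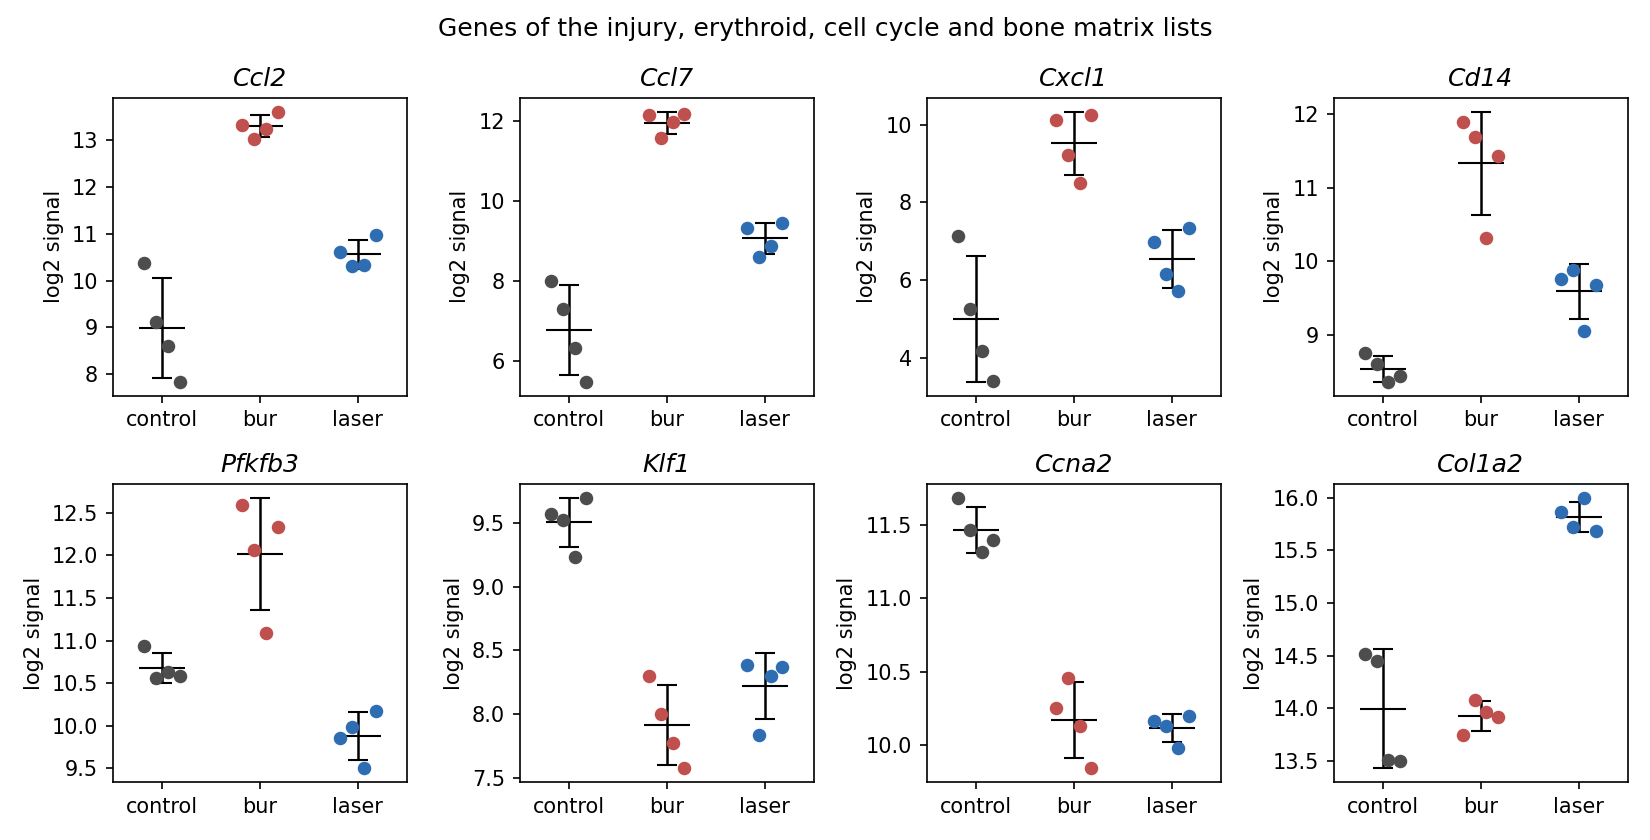
Quantile normalized log2 signal (y axis) of 8 genes on each array of the control, bur and laser groups (x axis), with the mean and SD of the 4 arrays as a dash and bar. Ccl2 has means of 8.98 in control, 13.30 in bur and 10.56 in laser, and Klf1 9.50, 7.91 and 8.22. Col1a2 stands at 14.00, 13.93 and 15.82.

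The direct comparison of laser with bur asked how the 2 ways of opening the bone differ. Car4, a carbonic anhydrase, fell by 3.16 ± 0.66 (SE, n = 4 per group) on the log2 scale, Dmkn by 3.13 ± 0.75, Saal1 by 3.01 ± 0.64 and Cxcl1 by 2.98 ± 0.72. Acod1 fell by 2.95 ± 0.77 and Clec4d, a lectin receptor of myeloid cells, fell by 2.94 ± 0.63, and the adjusted p of these 6 genes lay between 0.00535 and 0.0164. Cxcl2, a neutrophil chemokine, had a log2 fold change of -3.42 ± 1.03 (adjusted p = 0.0314), but was not called without bur 1 (-3.02), bur 2 (-3.46), bur 4 (-3.32), laser 2 (-3.35), laser 3 (-3.21) or laser 4 (-3.43). Prh1, a salivary protein gene, had -3.88 ± 1.31 (adjusted p = 0.0493), with 1 laser and 3 bur arrays well above background (-3.43 with laser arrays held at the background limit), but was not called without bur 2 (-4.00), bur 3 (-3.29), bur 4 (-3.73), control 1 or control 3 (-3.88 each), laser 1 (-3.67), laser 2 (-3.74), laser 3 (-4.01) or laser 4 (-4.09), nor with normexp (-0.86), the authors' deposited values (-1.49), no filter on dim probes or the mean of a gene's probes (-3.88 each). Under normexp the log2 fold changes were -2.00 for Dmkn, -1.71 for Acod1 and -1.96 for Clec4d, each still called.

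Of 20 inflammatory cytokines and chemokines, 11 fell, 1 rose and 8 did not pass (13 when adjusted over the list alone). Ccl3 was 6.51-fold, Ccl2 6.67-fold and Ccl7 7.42-fold lower in laser than in bur bone, while Lif, a cytokine of the interleukin-6 family chosen after its value was seen, was at least 2.17-fold higher, with no bur array well above background. By camera the list had adjusted p = 0.00356, and adjusted p = 0.70 with an estimated correlation. Of 13 monocyte and macrophage markers, 7 fell and 6 did not pass (7 when adjusted over the list alone), with Cd14 3.33-fold and the integrin Itgam 3.08-fold lower. Lyz2, a lysozyme gene chosen after its value was seen and counted as lower (-0.88 log2), had a second probe called higher (1.94). That list had camera adjusted p = 0.00218, and adjusted p = 0.544 with an estimated correlation. Of 16 hypoxia and glycolysis genes, 12 fell and 4 did not pass (12 lower and 1 higher when adjusted over the list alone). Pfkfb3, an activator of glycolysis, was 4.41-fold and the glycolytic enzyme Eno1 2.31-fold lower. The second Pfkfb3 probe gave -1.18 log2, against -2.14, and was also called. The 3 Eno1 probes gave -1.21, -0.45 and -1.24 log2, the second not called. Camera gave adjusted p = 0.000182, and adjusted p = 0.723 with an estimated correlation.

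Of 14 interferon-stimulated genes, 9 fell and 5 did not pass (13 when adjusted over the list alone), with Ddx58 at -1.60 log2 (-0.87 with normexp). The interferon list had camera adjusted p = 0.000202, and adjusted p = 0.683 with an estimated correlation. Of 16 osteoblast and bone matrix genes, 1 rose and 15 did not pass (1 when adjusted over the list alone), namely Col1a2, which was 3.70-fold higher in laser than in bur bone. For that list camera gave adjusted p = 0.0434, and adjusted p = 0.755 with an estimated correlation, and it was not called without bur 1 (adjusted p = 0.0900), bur 2 (0.102), laser 1 (0.102) or laser 2 (0.060).

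Of the 8 genes that the naming rule took as highest in laser against bur bone, 6 were also among the 8 it took against control. Both comparisons use the same laser arrays, on their own slide, which by itself makes such an overlap likely. Mcc was at least 199-fold, Ovch2 at least 66.7-fold and Id3 at least 19.3-fold higher, with no bur array well above background. The brightest Mkx probe was at least 116.5-fold higher, with no bur array well above background for it. Krt80, which 1 bur array read well above background, was 108-fold, Foxe1 51.2-fold, Fam155b 45.8-fold and Marcksl1, an actin-binding protein gene, 39.6-fold higher, and the adjusted p of the 8 genes was at most 1.12e-05. The other Marcksl1 probe gave 0.30 log2 and the other Mkx probes 1.59 and -0.11, of which the 1.59 was called and the others were not. Mcc, Ovch2, Id3 and Krt80 had only 1 kept probe each, so their folds could not be checked in this way. With normexp the log2 fold changes were 4.66 for Mcc, 2.79 for Ovch2, 1.43 for Id3, 3.81 for Mkx and 4.37 for Krt80, and with the authors' deposited values Marcksl1 gave 2.67, each still called. The normexp values of Mcc, Ovch2, Id3 and Mkx lay below their bounds, which are 7.64, 6.06, 4.27 and 6.86 in log2.

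In all, 4224 genes differed between laser-ablated and bur-drilled bone, 1898 higher and 2326 lower, while 5500 genes had groups that did not overlap (33.6%, where chance gives 2.86%). Higher genes outnumbered lower ones among the 1856 called by at least 2-fold (1185 higher, 671 lower) and under 75th percentile scaling (2431 higher, 2176 lower). Of the called genes, 577 were not well above background on any bur array, and 0 were not on any laser array. Here too the excess of higher genes at 2-fold cannot be told apart from better detection on the laser arrays. The number of lists called, 5 of 25, was matched or passed in 26 of the 35 splits of these 8 arrays. With an estimated correlation, camera called 0 lists in each comparison, with an unadjusted p under 0.05 for 4 lists in bur against control, 1 in laser against control and 0 in laser against bur, whereas fry called 10, 9 and 5. Fry tests whether the genes of a list move on balance 1 way, without setting them against other genes. Its 10 were those of camera in bur against control. In laser against control it called the 5 of camera and the periosteal, Wnt target, oxidative phosphorylation and chondrocyte lists, and in laser against bur the 4 lower lists and the BMP and TGF-beta list (fry adjusted p = 0.00205, higher) but not the osteoblast list (0.122). In that BMP and TGF-beta list 2 genes were called higher and 3 lower, and the median log2 fold change was -0.00175. Id3 stood at 6.01 log2, or 1.43 with normexp. The fry call therefore does not show that the list as a whole was higher.

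Several lists held genes that moved in opposite directions. Of 14 neutrophil markers, 3 were higher and 1 lower in bur than in control bone, 4 and 0 in laser than in control bone, and 4 and 2 in laser than in bur bone (4, 4 and 7 when adjusted over each list alone), with camera adjusted p = 0.489, 0.624 and 0.299. Trem1, an activating receptor of myeloid cells, rose 3.61-fold after drilling and was 4.19-fold lower after laser than after drilling. S100a9, a calcium-binding protein of neutrophils, was 1.87-fold higher in laser than in control and 2.66-fold higher in laser than in bur bone. In bur against control S100a9 had a log2 fold change of -0.51 (limma adjusted p = 0.0386), a call that hung on single arrays. Camp, an antimicrobial peptide gene, was 2.89-fold higher in laser than in bur bone, but its second probe gave -0.14 log2 and the mean of the probes 0.69, neither called. Outside the naming rule, S100a8 (1.16 log2) was the last of the 4 higher and Csf3r (-1.21) of the 2 lower in laser against bur, both chosen after their values were seen, and the second S100a8 probe gave -0.46 and was not called. S100a8 was also among the 4 higher in laser against control (0.86 log2), but there its second probe was called lower (-0.97), the mean of the probes gave -0.0534, not called, and without laser 4 the value of 0.78 was not called. Of 12 osteoclast markers, 2 rose and 1 fell in bur against control, 1 and 1 in laser against control, and 2 and 2 in laser against bur (3, 2 and 5 when adjusted over each list alone), with camera adjusted p = 0.837, 0.938 and 0.849. Ctsk, the collagen-degrading protease of osteoclasts, was 2.39-fold higher in laser than in bur bone.

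Of 9 osteocyte markers, 2 were higher and 0 lower in bur than in control bone, 3 and 0 in laser than in control, and 0 and 0 in laser than in bur bone (2, 3 and 0 when adjusted over each list alone), with camera adjusted p = 0.159, 0.159 and 0.849. Pdpn, a membrane glycoprotein of early osteocytes, rose 7.54-fold after drilling. In laser against bur bone it had a log2 fold change of -1.74, which was not called (adjusted p = 0.0794) except without control 1, where the value was again -1.74, and under 5 other settings, although its second probe alone was called (-2.01). Mepe and Phex, which regulate mineralization, rose 3.34-fold and 4.04-fold in laser against control, and without control 1 and control 4 neither was called (log2 1.49 and 1.52), while with normexp Phex gave 0.52. Mepe also rose 2.46-fold in bur against control (limma adjusted p = 0.0339), a call that hung on single arrays. Phex was well above background on 1 of 4 control arrays. Of 9 Wnt target genes, 1, 2 and 1 were higher in the 3 comparisons and 0 lower (1, 2 and 1 when adjusted over each list alone), with camera adjusted p = 0.897, 0.246 and 0.227 and fry adjusted p = 0.593, 0.0270 and 0.0992. In laser against control, where fry called the Wnt target list higher, its median log2 fold change was 0.54. Of 9 secreted Wnt antagonists, 1, 2 and 1 were higher and 0 lower (0, 2 and 1 when adjusted over each list alone), with camera adjusted p = 0.743, 0.505 and 0.779 and fry adjusted p = 0.323, 0.168 and 0.749.

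The remaining lists are given in the order bur against control, laser against control and laser against bur. In the 18 YAP and TAZ target genes, 5, 3 and 0 were higher and 1, 1 and 2 lower (10, 2 and 1 when adjusted over each list alone), with camera adjusted p = 0.159, 0.577 and 0.505. In the 13 heat shock genes, 3, 2 and 0 were higher and 0, 0 and 1 lower (3, 1 and 1), with camera adjusted p = 0.624, 0.708 and 0.897. In the 14 oxidative phosphorylation genes, 0, 1 and 1 were higher and 1, 5 and 0 lower (0, 7 and 0), with camera adjusted p = 0.119, 0.167 and 0.875 and, in laser against control, fry adjusted p = 0.0158. In the 12 lymphocyte markers, 1, 0 and 0 were higher and 1, 0 and 1 lower (2, 0 and 1), with camera adjusted p = 0.427, 0.945 and 0.427. In the 12 endothelial markers, 0, 5 and 2 were higher and 1, 1 and 0 lower (0, 6 and 1), with camera adjusted p = 0.624, 0.259 and 0.330. In the 8 epidermal markers, 1, 4 and 2 were higher and 0, 0 and 2 lower (1, 4 and 5), with camera adjusted p = 0.246, 0.330 and 0.897. In the 8 skeletal muscle markers, 2, 2 and 2 were higher and 0, 0 and 2 lower (2, 2 and 4), with camera adjusted p = 0.299, 0.551 and 0.783. In the 3 chondrocyte markers, 0, 1 and 2 were higher and 0 lower (0, 1 and 2), with camera adjusted p = 0.897, 0.246 and 0.265 and, in laser against control, fry adjusted p = 0.0158. Of the 5 adipocyte markers 0 were called by limma in any comparison over all genes or over the list alone (0, 1 and 0 had an unadjusted p under 0.05), with camera adjusted p = 0.452, 0.401 and 0.875 and fry adjusted p = 0.601, 0.387 and 0.745. Members of these counts outside the naming rule, chosen after their values were seen, were Rbms3 (0.91 log2, its second probe 0.68 and not called) and Nuak2 (1.30, or 1.27 with control arrays held at the background limit), with 3 and 2 control arrays well above background, among the YAP and TAZ targets in bur against control. In laser against control they were Pecam1 (0.73) and Cldn5 (0.50) among the endothelial markers and Cox4i1 (-0.53) and Cycs (0.42, its second probe 1.75 and called) among the oxidative phosphorylation genes.

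For lists called in another comparison, the remaining counts were as follows. Of 16 osteoblast and bone matrix genes, 3 were higher in bur than in control bone (0 when adjusted over the list alone, camera adjusted p = 0.113). In laser against bur, 4 of 19 cell cycle genes were higher (4 when adjusted over the list alone, camera adjusted p = 0.0507) and 1 of 12 erythroid markers (0, camera adjusted p = 0.246). Of 15 matrix genes 2 were lower (2, camera adjusted p = 0.875), of 15 BMP and TGF-beta genes 2 were higher, Id3 and Ltbp2, the latter at 0.75 log2 and chosen after its value was seen, and 3 lower (8, camera adjusted p = 0.585), and of 12 periosteal markers 1 was higher (0, camera adjusted p = 0.897). Of 7 neural markers 2 were higher (2, camera adjusted p = 0.246), namely Gfap, for which no fold is given because no bur array was well above background and the laser mean lay below the background limit, and Mag, 3.07-fold higher with 3 bur arrays well above background and 0.56 log2 under normexp. In laser against bur the median, mean and test direction of a list differed in sign for the osteocyte, Wnt antagonist, matrix, BMP and TGF-beta, periosteal and epidermal lists, and in laser against control for the neutrophil list, none of them called by camera.

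Bur drilling and laser ablation were set against the same control arrays, which by itself makes their fold changes alike. Over 16375 genes the log2 fold changes of the 2 treatments correlated with r = 0.513 across genes, beside 0.501 ± 0.0123 (SD) in 50 simulations of unchanged groups against these controls. The covariance was 0.343, beside 0.0653 in the simulations, a difference of 0.278. Of the called genes, 870 were higher and 1099 lower in both treatments and 90 went opposite ways. Independent lists of these sizes would share 409 and 258, a count that leaves out the shared controls. The simulations shared 0, but their groups were unchanged, so few genes could be called there. Neither count therefore shows how much of the overlap the shared controls account for. With the controls split 2 and 2 in all 6 ways, r lay between 0.235 and 0.411 and the covariance between 0.193 and 0.293, with 279 to 553 genes higher and 542 to 748 lower in both and 29 to 385 opposite. The 385 came with control 1 and control 2 set against bur and the other controls against laser, and the other splits gave at most 103. Independent lists of the sizes called in each split would share 136 to 425 higher and 81.2 to 266 lower genes. Each split, in which the treatments shared no control array, passed its own count in both directions.

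**Figure D4:**
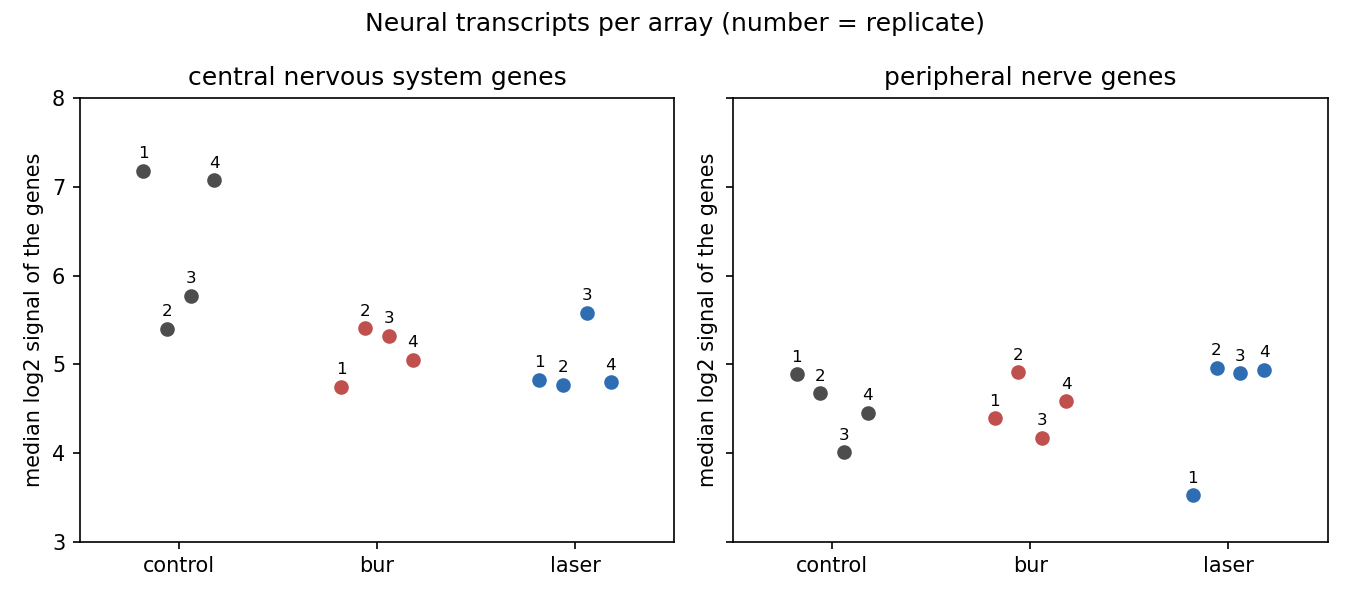
Median log2 signal per array (y axis) of 16 central nervous system genes and of 6 peripheral nerve genes, in the control, bur and laser groups (x axis); each point is an array and its number the replicate. Control 1 and control 4 stand at 7.18 and 7.08 for the central nervous system genes and all other arrays between 4.75 and 5.78.

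The authors' deposited tables, in which several entries can name 1 gene, called 6603 entries for bur against control (3862 higher, 2741 lower), 8270 for laser against control (4474 higher, 3796 lower) and 6687 for laser against bur (3030 higher, 3657 lower). Taken to 14937 genes and fitted as here, the authors' deposited log2 values called 4624, 5410 and 4107 genes. Over the 14928 genes in both sources, log2 fold changes of the authors' deposited tables correlated across genes with those computed here at r = 0.903, 0.897 and 0.899 in these comparisons.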

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

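The tests of a slide or scan difference on single probes, of dim probes, of the quantile step and of the laser treatment were chosen after the results they measure were seen, as were the 95% intervals set beside the other tests and the reading that a confounded slide leaves its explanation open.

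A single array stood far from the other 3 of its group in 18 of 318 groups of 4 arrays tested, where chance gives about 1 in 20 groups, or 15.9. Control 1 had 557 outlier spots, against at most 332 on another control array. Bur 4 had a replicate-probe variation of 7.64%, against at most 5.86%. Bur 4 also had the lowest score of its group for the neutrophil list (-0.66, nearest -0.02) and the cell cycle list (-1.40, nearest -1.02), and control 2 the highest for the chondrocyte list (0.77, nearest -0.23).

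Among genes (log2 level, then the nearest array of the group), control 1 was lowest for Aqp7 (1.16, 4.36) and control 3 highest for Mepe (12.99, 12.02). Control 4 was lowest for Csf3 (6.78, 7.91) and Rps19l3 (5.20, 5.50). Bur 2 was highest for Slc7a10 (4.34, 0.64). Bur 4 was highest for Csf3 (6.77, 6.43), Gfap (0.71, 0.66) and Ovch2 (2.27, 1.21). Laser 1 was highest for Ddx58 (5.88, 5.36) and laser 2 lowest for Klf1 (7.84, 8.30). Laser 3 was highest for Bcan (3.32, 2.40) and lowest for Hk2 (6.99, 7.64) and Igfbp2 (3.21, 3.91).

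Probes of the same gene moved in opposite directions far more often in the laser comparisons. In laser against control 152 genes had probes called both higher and lower, in laser against bur 110, and in bur against control, within 1 slide, 5. Dim probes are argued against as the whole cause, since 126 such genes were left among probes well above background on 12 of 12 arrays. Isoforms that differ between laser and control bone are argued against as the whole cause too, because 371 pairs of probes that overlap in position correlated at 0.682 in laser against control and at 0.914 in bur against control, a difference of 0.232 (95% interval 0.123 to 0.354). A difference between the slides or scans that acts on single probes remains a candidate explanation and cannot be told apart from the laser treatment, as each group of the laser comparisons lies on its own slide.

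Neural transcripts were high in control 1 and control 4. The median log2 signal of 16 central nervous system genes was 7.18 and 7.08 there, 5.40 and 5.78 in control 2 and control 3, and 4.75 to 5.58 on the bur and laser arrays. Brain tissue taken along with the bone, which lies against the calvaria, may be a source. Of the 16 genes, 50% had their 2 highest control values in these 2 arrays, where chance gives 16.7%, which leaves it open, and Snap25 (8.78, 7.87, 1.60 and 7.59 in controls 1 to 4) was high in control 2 as well. Peripheral nerve of the bone or periosteum stays open too, with 16.7% of only 6 genes (exact 95% interval 0.421% to 64.1%), and no explanation by the study's own groups was tested.

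Cytokine, macrophage, hypoxia and interferon lists were called lower in laser than in bur bone by camera with its preset correlation, and by fry, but 0 of the 4 with an estimated correlation (adjusted p = 0.70, 0.544, 0.723 and 0.683). A slide difference that acts on single probes is argued against as the whole cause, since the 29 other probes of 21 of the 63 members tested had a median log2 fold change of -1.0 (95% interval -1.18 to -0.49), with 23 lower. The interval leaves out values within 0.3 of 0, which this cause predicts, but reaches just past the -0.5 set beforehand as the bound against it. The quantile step of the between-array normalization is argued against as well, as 4 of 4 list calls, with the preset correlation, were kept when 75th percentile scaling took its place. The laser treatment itself and a slide effect on whole samples remain possible explanations of these calls that cannot be told apart, because 0 slides hold both laser and bur arrays.

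For the number of genes called, 1 of 35 splits, the real one, gave as many in each comparison. This is the smallest share that 35 splits can give, so it argues against chance but cannot exclude it. The other splits mix arrays of both groups, which widens the spread within their groups and can lower their counts. The real counts were 3837, 5637 and 4224 for bur against control, laser against control and laser against bur, and the highest of the other splits gave 8, 38 and 4. For the number of lists called by camera with its preset correlation chance cannot be excluded, since 7, 28 and 26 of the 35 splits gave as many as the real 10, 5 and 5, with 14, 12 and 15 in the highest other split.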

How the results depend on the processing

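Leaving out control 1 and control 4 and counting genes with every probe called the same way were chosen only after the results were seen. The slide as a block was not run, since it adds nothing within 1 slide and cannot be fitted across them. Signal over background limits the dim genes. In laser against control 564 called genes were not well above background on any control array, against 1 on any laser array.

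Where not stated otherwise the cause was not tested. Sost in bur against control (0.20) turned to -0.14 with 75th percentile scaling, -0.0125 with the authors' deposited values and -0.35 without control 1 and control 4, and lay between -0.18 (without control 4) and 0.49 (without bur 1) with 1 array left out. With 1 array left out it lay between -0.82 and -0.14 in laser against control and between -0.93 and -0.33 in laser against bur. In laser against control it was -0.99 without control 1 and control 4 and -0.06 with array weights. None of these passed the threshold. Other genes that turned were Sox9 in bur against control (-0.13) and Tnnt3 in laser against control (-0.0521) with 75th percentile scaling, S100a8 (-0.0534) in laser against control over the mean of the probes, and Il2rb (-0.0317) and Pvalb (0.20) in laser against control without control 1 and control 4. With 1 array left out, Cfd in laser against control ranged from -0.31 to 0.13, Wif1 in laser against bur from -0.0503 to 0.75 and Frzb in laser against bur from -0.0610 to 0.49.

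The count of genes for bur against control was 2476 with only the 2 groups fitted and 2353 without control 1 and control 4, which tests fewer arrays, with 2126 of these among the 3837. By at least 2-fold, which is a stricter threshold, 1794, 2514 and 1856 genes were called in bur against control, laser against control and laser against bur, of which 1056, 1740 and 1185 were higher. With every probe tested on its own 8930 and 7426 probes were called in laser against control and laser against bur, since more probes than genes were tested, and 472, 425 and 302 genes had every probe called the same way. With 1 array left out the counts ranged from 2756 to 4110, 4202 to 5736 and 3005 to 4574. Of calls in laser against bur, 32.7% were higher among probes well above background on all 12 arrays, against 44.9%.

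For gene lists, camera with an estimated correlation called 0, 0 and 0, with 4, 1 and 0 at an unadjusted p under 0.05, fry called 9 in laser against control, and its test for change in either direction 19, 20 and 18. With 1 array left out 9 to 12, 5 to 7 and 5 to 6 lists were called. Of list calls under other settings 213 were kept and 7 lost, and 231 and 9 with 1 array left out. Those lost were the periosteal, neural and BMP and TGF-beta lists in bur against control and the osteoblast list in laser against bur. The correlation of both treatments' fold changes ranged from 0.485 to 0.566 with 1 array left out.

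With the replicate number as a block 3990, 5934 and 4406 genes and 10, 6 and 6 lists were called. The numbers were not taken as pairs, since not every correlation passed 0.1: deviations of samples of 1 number correlated at 0.085 to 0.20 between bur and control, -0.067 to 0.35 between bur and laser and -0.105 to 0.25 between control and laser, and 8 of 12 arrays correlated best with their own number, where chance gives 3. This is a hint from the data, not the design, and the number is also the row on the slide for 12 of 12 arrays.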

Other observations

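The tests of Gene Ontology terms, whose annotation is that of the authors' deposited tables, were all chosen after the data were seen. Camera with its preset correlation was run on 1816 terms over 12691 genes.

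In bur-drilled against control bone, chromatin and heme genes were lower. Of 51 nucleosome genes, 30 fell and 0 rose (median log2 fold change -0.76, adjusted p = 5.98e-11), and of 41 genes of the condensed chromosome kinetochore, the site that spindle fibres bind, 23 fell and 1 rose. Each term given here for this comparison had adjusted p = 0.907 with an estimated correlation. Of 15 genes of heme biosynthesis 12 fell (median -1.14, adjusted p = 4.28e-08). Toll-like receptor signaling had 10 of 16 genes higher (median 1.19, adjusted p = 0.00101), lymphocyte chemotaxis 9 of 16 (median 1.77, adjusted p = 0.0112) and neutrophil chemotaxis 23 higher and 4 lower of 48 (adjusted p = 0.00674). Positive regulation of osteoblast differentiation had 15 of 45 genes higher (adjusted p = 0.00235), positive regulation of bone mineralization 10 of 26 (adjusted p = 0.00512) and zinc ion transmembrane transport 8 of 15 (adjusted p = 0.00512).

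In laser-ablated against control bone, matrix genes were higher. The proteinaceous extracellular matrix had 57 genes higher and 7 lower of 159 (adjusted p = 0.000235). It had adjusted p = 0.998 with an estimated correlation, as had each term given here for the laser comparisons. Collagen fibril organization had 18 higher of 37 (median 0.83, adjusted p = 0.000515), basement membrane 25 higher and 4 lower of 68 (adjusted p = 0.0203) and cartilage development 14 higher and 1 lower of 40 (adjusted p = 0.0240). The nucleosome term was lower, with 24 lower and 2 higher of 51 (adjusted p = 0.000235). Olfactory receptor activity, a set of genes of the nose, was higher against control (22 higher and 3 lower of 57, adjusted p = 0.00280) and against bur (22 and 5, adjusted p = 0.000671), on the slide whose arrays had the higher signal. The cytosolic large ribosomal subunit was also higher against both, with 31 higher and 4 lower of 75 (median 0.19, adjusted p = 0.00228) and 27 and 4 (median 0.08, adjusted p = 0.000671). Of its genes, 4 against control and 6 against bur had probes called both higher and lower, and 1 of these was counted as higher and 2 as lower in each. Over the mean of a gene's probes 37 were higher and 1 lower against control (median 0.33, adjusted p = 6.82e-07) and 34 and 2 against bur (median 0.30, adjusted p = 3.11e-12).

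In all, 119 terms were called in bur against control (40 higher, 79 lower), 48 in laser against control (17 higher, 31 lower) and 4 in laser against bur (4 higher). With an estimated correlation camera called 0 terms in each comparison, with 87, 62 and 29 at an unadjusted p under 0.05 and lowest adjusted p-values of 0.907, 0.998 and 0.998.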
